A study of Mus musculus with 2 samples.

How the data were processed

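PolyA RNA of the mouse MEL cell line was sequenced in 2 libraries, which the labels number as biological replicates 1 and 2 of 1 group. No between-group comparison exists, and each value is given per library or as a mean with its SD (n = 2). Nothing in the labels says whether the cultures were grown separately beyond that numbering.

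Per the text deposited with each library, values were made from alignments to the transcriptome of assembly mm10 with GENCODE annotation M4, with 1 gene table and 1 transcript table per library. The aligner, the quantifier, their versions and the strand setting are not given in the sources used here. The column names are those that RSEM writes. Per the file headers, the authors deposited an expected count per gene and transcript, an estimate of assigned reads that need not be whole. Per the file headers, the authors also deposited TPM and FPKM, which rescale those counts for transcript length and library total. The deposited TPM were scaled over every row of a table, the rows of phage phiX174, spike-ins and numeric identifiers included. The deposited posterior mean TPM adds a prior to each transcript and is above 0 even for a gene without a count. The credibility bounds that the authors deposited lie around that posterior mean and not around TPM. The deposited transcript tables also give each transcript's percent of its gene's TPM, and the shares given here were computed from TPM.

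Each gene table held 43346 rows with mouse gene identifiers, of which 42462 were matched to a symbol by identifier without its version. Positions and gene types are those of GENCODE M21 on the same assembly (mm10, GRCm38), and 21474 matched rows were protein-coding. The 884 rows without a match entered no gene list and no protein-coding count. The phiX174 row, 96 spike-in rows and 26248 rows with numeric identifiers name no mouse gene. They were left out of mouse gene totals, library sizes and tests. They held 85.1% and 0.151% of all expected counts in replicate 1 for phiX174 and the numeric rows, and 81.4% and 0.0471% in replicate 2.

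Expected counts were rounded to whole numbers for count models. TMM scaling and common dispersion were computed in edgeR 4.0.16 from an intercept-only model, and median-ratio size factors in DESeq2 1.42.0, both under R 4.3.3. A chi-square over genes compared the libraries for protein-coding genes with at least 10 summed counts. Log2 ratios used TMM scaling and a prior count of 2. A 2-fold difference was called without a p-value among protein-coding genes with a mean count of at least 100. Where a library held 0 counts, the fold is a lower bound against 3 scaled counts in that library. Other tables were computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

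The lists of genes, the comparisons and the rule for named genes were fixed before the data were examined. The rule took 2 to 6 members of each list with the highest mean TPM, members of special note such as those below a TPM of 0.1, and the 20 most abundant genes. Nfe2, Cdkn2a, Pgk1, Atf3 and Rplp0 each stood in a pair of lists. It also took the 10 protein-coding genes with the largest ratio in each direction at a mean count of at least 100, and transcripts with at least 10% of the TPM of 20 fixed genes. A list's median TPM was placed among 10000 random lists of the same size drawn from protein-coding genes. A list's median log2 ratio was placed among 10000 random lists matched on mean count in 50 bins. It covered protein-coding members with an expected count of at least 0.5 in either library, for lists with at least 5 such members. Ties counted 0.5 in each percentile. The bins, the treatment of ties and the member minimum were set after the counts had been seen. Random lists from coarser bins, added later, placed the same lists outside the central 95%.

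The procedures were tested on simulated data. Counts drawn without extra spread gave a chi-square of 1.07 per degree of freedom over 1389 genes. A biological coefficient of variation set at 0.5 was estimated at 0.506 over 1361 genes. Of 200 genes with at least 20 summed counts changed 4-fold, 92.5% came out at least 2-fold apart in the right direction. Of 200 random lists of 15 genes, 1.00% fell outside the central 95% of matched lists, and 74.5% lay above that range once each member was raised 2-fold, out of 7191 genes.

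The design had assumed libraries of ordinary depth. Mouse gene counts came to 35277 and 40648, and a protein-coding gene with exactly 1 count had a median TPM of 5.58 in replicate 1 and 5.93 in replicate 2. A TPM of at least 1 therefore means little more than 1 count. A count of 0 allows up to 3 counts, a one-sided limit, or 0.00850% and 0.00738% of mouse gene counts. Intervals are exact two-sided Clopper-Pearson intervals at 95%, which at a count of 0 would reach 0.00154% and 0.00169% of all counts where that limit gives 0.00125% and 0.00137%, and intervals and floors cover counting error only, since reads carried no molecular identifiers. Genes that share sequence with near-identical copies are uncertain, as are antisense genes, since the strand setting is not stated.

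Shared sequence was searched with words of 31 bases from M21 transcripts for 147 genes, and genes that held at least 25% of another gene's words counted as its copies. Alternatives covered thresholds, units, scalings, pseudocounts, filters, denominators, backgrounds and the removal of each replicate.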

Results

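MEL cells are an erythroleukaemia line of the mouse, blocked at an early stage of red cell formation, and the labels describe the line as a leukaemia counterpart of human K562 cells. PolyA RNA was profiled in 2 biological replicates. The deposited expected counts totalled 239704 in replicate 1 and 218564 in replicate 2. Mouse genes held 35277 of these in replicate 1, or 14.7% (95% exact interval 14.6 to 14.9), and 40648 in replicate 2, or 18.6% (18.4 to 18.8). Nearly all other counts lay on phage phiX174.

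Most listed erythroid transcription factor and cell cycle genes were detected at this depth, and globin genes mostly were not. Of 21474 protein-coding genes, 5388 reached a TPM of 1 in replicate 1 and 5288 in replicate 2. Both libraries shared 3484 of them, against 1327 for independent lists of these sizes. A single library without its replicate thus gave over 1.5 times the shared count.

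The erythroid transcription factors and cofactors were the best detected erythroid list, with 11 of 15 members at a TPM of at least 1 in both libraries. Their median mean TPM was 22.4, at percentile 100 of random lists of protein-coding genes. Most genes in such lists had no count, and among random lists of genes detected in both libraries the percentile was 56.1. That second background holds no undetected gene, while each fixed list kept its undetected members, which lowers its percentile. Ldb1, which bridges distal and promoter-bound factors (ENSMUSG00000025223.10, mm10 chromosome 19, 46031570 to 46045214), had 20 and 31 counts and a TPM of 238 ± 19.4 (SD, n = 2). Gata1, the main erythroid GATA factor (ENSMUSG00000031162.10, chromosome X, 7959260 to 7978071), had 57 counts in replicate 1 and 5 in replicate 2, with a TPM of 209 ± 243 (SD, n = 2). Its cofactor Zfpm1 had 6 and 9 counts and a TPM of 119 ± 70.6, most of it on a transcript not annotated as coding. Lmo2, a partner of Ldb1, had 76.1 ± 28.4. Ikzf1 stood at 37.5 ± 35.0. Klf1, an activator of adult globin genes, had 1 count in replicate 1 and 0 in replicate 2, and Sox6 had none.

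Haem synthesis genes reached a TPM of 1 in both libraries in 6 of 13 cases. The list had a median TPM of 11.7, at percentile 99.8, which rests on replicate 1: with replicate 2 alone the median was 0, at percentile 49.0. Among lists of detected genes it lay at percentile 5.6. Urod stood at 98.8 ± 103, Cpox at 80.7 ± 70.5 with 33 and 7 counts, and the ferrochelatase gene Fech at 23.7 ± 21.3. Alas2, the erythroid enzyme of the first step, had a single count in replicate 1. Among 13 genes of iron handling, 6 were detected in both libraries (median TPM 7.94, percentile 99.3, but 0.475 among detected genes and 96.9 on posterior mean TPM). The ferritin heavy chain gene Fth1 led them at 342 ± 59.6, with 20 and 23 counts, ahead of the haem oxygenase gene Hmox2 at 68.5 ± 26.3. The transferrin receptor gene Tfrc had 20.1 ± 6.87.

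Of 27 red cell membrane and late erythroid genes, 12 were detected in both libraries and 7 had no count (median TPM 6.03, percentile 99.9, but 0 among detected genes and 80.1 on posterior mean TPM). Carbonic anhydrase genes led the list. Car1 had 6 and 39 counts (TPM 272 ± 292) and Car2 17 and 4 (TPM 137 ± 148). Ermap followed at 81.2 ± 96.7, and the spectrin gene Spta1 had 9 counts in each library (22.6 ± 6.78). The glycophorin gene Gypa and the anion exchanger gene Slc4a1 lay at 0 in both libraries. Erythroid cytokine signalling genes were detected in 6 of 13 cases (median TPM 6.74, percentile 98.9, but 0.14 among detected genes and 85.4 on posterior mean TPM). Among them, Jak2 stood at 17.3 ± 2.99 with 6 and 7 counts. The erythropoietin receptor gene Epor stood at 14.7 ± 1.12 with 2 counts in each library. At such counts, an SD over 2 libraries does not give the counting error. Cish, with 1 count in each library, had 22.9 ± 26.1, and Kit, Mst1r and Bcl2l1 had 0 counts.

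Globin transcripts were close to absent from the counts. The adult alpha globin genes Hba-a1 and Hba-a2, near-identical copies whose reads cannot be divided with certainty, had 0 counts in replicate 1 and 3 each in replicate 2. Hbb-bs and Hbb-bt, the adult beta genes, had 0. The adult globin share of TPM was 0% in replicate 1 and 0.0182% in replicate 2. As a share of all counts it was 0%, which allows up to 0.00125%, and 0.00275%. Over mouse gene counts it was 0%, which allows up to 0.00850%, and 0.0148%. The median of the 4 adult genes lay at percentile 98.3 through those 6 counts alone, at 37.2 with replicate 1 alone, 49.8 among detected genes and 85.0 on posterior mean TPM. The 7 embryonic and theta globin genes had no count. The adult share of beta-like globin TPM has no value, since every beta-like gene was at 0.

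Genes linked to Friend virus leukaemia had a median TPM of 60.8 (percentile 100), with 6 of 9 detected in both libraries. Myc stood at 144 ± 121 and Mdm2 at 87.8 ± 124, the latter from 11 counts in replicate 2 alone. The tumour suppressor gene Cdkn2a had 9 counts in replicate 1 and 0 in replicate 2. Spi1, the ETS factor gene activated by the virus in many such tumours, had 3 and 4 counts (64.9 ± 52.4). Myb had 14 counts in each library (60.8 ± 2.57). Erg had no count. Stem and progenitor genes were detected in both libraries in 1 of 14 cases, Runx1 at 7.20 ± 6.81. Cd48 and Meis1 had 1 and 2 counts in a single library, and Cd34, Gata2 and the other members had none.

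Markers of other cell types were near absent, apart from Itgam in replicate 2. Of 76 such genes, 1 was detected in both libraries (1.32%), against 35 of 68 in the 4 erythroid lists of factors, haem synthesis, membrane and cytokine signalling (51.5%). Fisher's exact test gave a two-sided p of 1.89e-13, chosen after the data were seen and only a description, since genes are not independent replicates. Each list had a median of 0, as did 74.0% to 92.7% of random lists of these sizes. In single lists, the granulocyte and macrophage genes held counts only for Itgam, 0 and 14. Its TPM of 220 ± 311, from replicate 2 alone, was above the mean TPM of Gata1. The megakaryocyte genes held counts only for Gp5 (0 and 1) and the lymphocyte genes only for Lck (1 and 0). Mast cell genes held counts only for Hdc (2 and 0), and stromal, endothelial and epithelial genes only for Pdgfrb (2 and 1). The 10 genes of unrelated tissues, Alb and Gfap among them, had none. With 1 library alone, 3 of the 76 were detected against 43 or 46 of the 68. The 68 leave out the adult globins (0 of 4 detected in both), the embryonic and theta globins (0 of 7) and the iron genes (6 of 13). Among lists not tied to a cell type, glycolysis and hypoxia had 9 of 16, reference genes 10 of 14 and interferon response 1 of 10. The contrast therefore does not separate erythroid genes from genes not tied to a cell type.

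**Figure D1:**
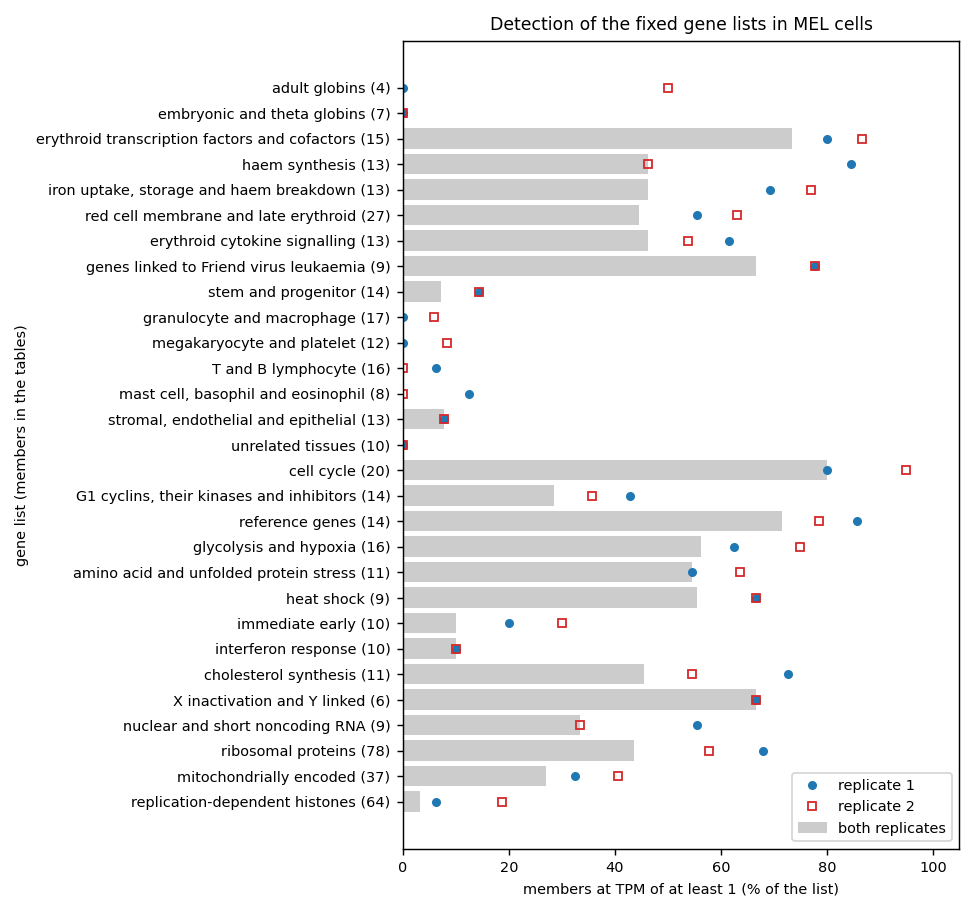
Percent of each fixed gene list at a TPM of at least 1 in MEL cells, with the number of members in brackets. Grey bars show members detected in both replicates, filled circles replicate 1 and open squares replicate 2. Cell cycle genes (16 of 20) and erythroid factors (11 of 15) lie highest, and lists of other cell types at or near 0.

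The cells carried transcripts of dividing cells. Of 20 cell cycle genes, 16 were detected in both libraries (median TPM 52.7, percentile 100). The helicase subunit gene Mcm6 led at 174 ± 102, with 9 and 51 counts, followed by Cdk1 at 159 ± 93.7 and Aurka at 113 ± 64.7. The cyclin genes Ccnb1 and Ccna2 stood at 104 ± 90.4 and 103 ± 87.8, and Top2a at 103 ± 7.86. The proliferation marker Mki67 had 68 and 85 counts. E2f1 had no count.

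Reference genes were uneven. Eef1a1 led them at 9915 ± 8476, followed by Rplp0 at 856 ± 497, Actb at 588 ± 280 and B2m at 206 ± 185, and 10 of 14 were detected in both libraries (median TPM 36.8, percentile 100, and 93.5 among detected genes). Gapdh, among the most abundant transcripts of most cells, had 1 count in replicate 1 and 0 in replicate 2, and Pgk1 had 0 in both. Of 78 ribosomal protein genes, 34 were detected in both and 15 held no count of at least 1 in either (median TPM 64.6, percentile 100). Rps17, at 1410 ± 1693, and Rpl28, at 1209 ± 1710, led them. Rpl28 had 143 counts in replicate 1 and 0 in replicate 2.

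Of the 20 most abundant mouse genes, 8 were mitochondrially encoded. Mitochondrially encoded genes made up 6.57% ± 2.89 of TPM (SD, n = 2) and 1.85% ± 0.574 of all expected counts. Nuclear copies of these genes are not part of that share, so it depends in part on how reads were divided between copies. Ribosomal protein genes made up 1.76% ± 0.513 of TPM and 0.378% ± 0.111 of counts. Replication-dependent histone genes, whose transcripts mostly lack polyA tails, had 0.0658% ± 0.0786 of TPM and 0.0153% ± 0.0185 of counts, and 2 of 64 were detected in both libraries. The histone values rest mostly on replicate 2. Shares of TPM were 0.0102% in replicate 1 and 0.121% in replicate 2, with 4 and 12 members detected. The 10 most abundant genes had 10.4% ± 4.20 of TPM and 3.07% ± 1.29 of counts. Over mouse genes alone, the mitochondrial share of TPM was 14.2% ± 4.34. Of 37 mitochondrially encoded genes, 10 were detected in both libraries, and 20 held no count of at least 1. Those with counts included 13 protein-coding genes and both ribosomal RNA genes.

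Among the 20 most abundant genes, mt-Co2 (22767 ± 32197 TPM), mt-Co3 (9196 ± 12981), mt-Atp6 (4880 ± 6901), mt-Cytb (4273 ± 3006), mt-Co1 (3469 ± 450) and mt-Nd4l (2968 ± 4198) were protein-coding mitochondrial genes. The mitochondrial ribosomal RNA genes mt-Rnr1 and mt-Rnr2 had 8803 ± 5277 and 4875 ± 3020. A group of 3 unprocessed pseudogenes on chromosome 1 that share sequence with mitochondrial genes was among them, Gm28437 (10462 ± 14796), Gm29216 (10395 ± 11876) and Gm10925 (4556 ± 6443). Nuclear genes were Eef1a1, Nanog (4643 ± 6566), Hsp90ab1 (4266 ± 5751) and Hspa9 (2089 ± 1879). Noncoding genes and processed pseudogenes were Gm42418 (6130 ± 5215), Rpl30-ps9 (3185 ± 2617), Gm8172 (3159 ± 3663) and n-R5s1 (2375 ± 3358). ENSMUSG00000045999.9, which had no match in the annotation used, was even between libraries, at 16864 ± 1549 TPM and 1605 and 1641 counts.

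Abundant genes differed widely between the replicates. Of 16 protein-coding genes with a mean count of at least 100, 12 were at least 2-fold apart, 8 higher in replicate 2 and 4 lower. The balance depended on the filter, with 157 higher and 154 lower at a mean count of at least 10, and 927 higher and 1403 lower without a filter. Nanog, a pluripotency factor gene (ENSMUSG00000012396.8, chromosome 6, 122707489 to 122714633), had 1455 counts in replicate 2 and 0 in replicate 1, at least 475-fold higher. In the same direction were mt-Co2 (0 and 2128 counts, at least 695-fold), mt-Atp6 (0 and 454, at least 148-fold) and the zinc finger gene Zfp971 (0 and 283, at least 92.4-fold). The chaperone gene Hsp90ab1 (22 and 347 counts), the DNA methyltransferase gene Dnmt1 (41 and 229), Eef1a1 and mt-Cytb had log2 ratios of replicate 2 over replicate 1 of 3.83, 2.40, 2.39 and 1.38.

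Dcaf17 (ENSMUSG00000041966.14, chromosome 2, 71055328 to 71099142) had 533 counts in replicate 1 and 0 in replicate 2, at least 181-fold lower in the latter. Counts of mt-Co3 were 1104 and 0.93, a ratio of 1127 with a counting interval of 202 to 44567, and those of Aldoart1, an aldolase retrogene, 285 and 6 (log2 ratio -5.19). The mitochondrial chaperone gene Hspa9 had a log2 ratio of -1.14. Pabpc1, mt-Nd4, mt-Nd5 and mt-Co1 were within 2-fold. These ratios compare 1 library with 1 library and have no replicate check. Several mitochondrial genes share sequence with nuclear copies, so their single values are uncertain.

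**Figure D2:**
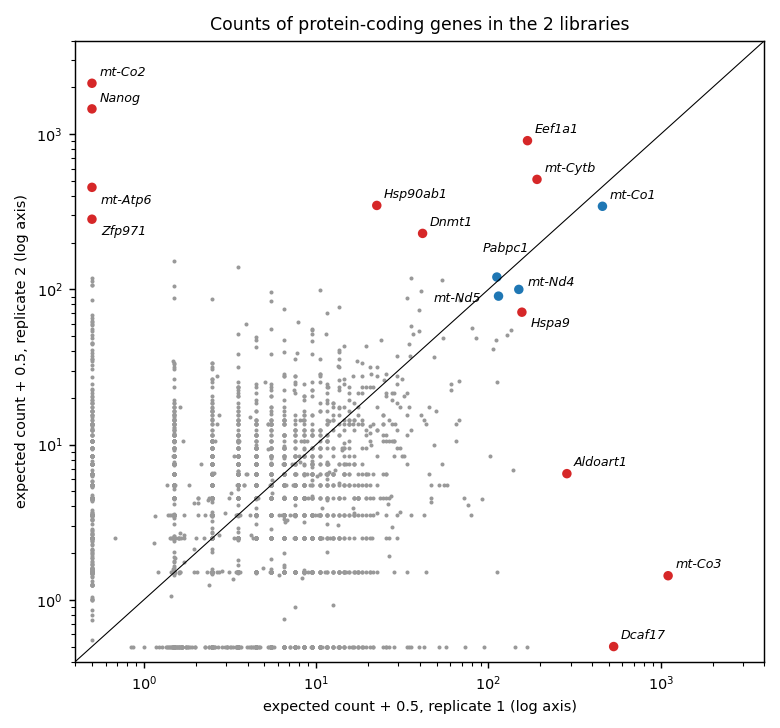
Expected counts of protein-coding genes with any count in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes after adding 0.5, with the line of equal counts. Named points are the 16 genes with a mean count of at least 100, red for the 12 at least 2-fold apart and blue for the other 4.

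**Figure D3:**
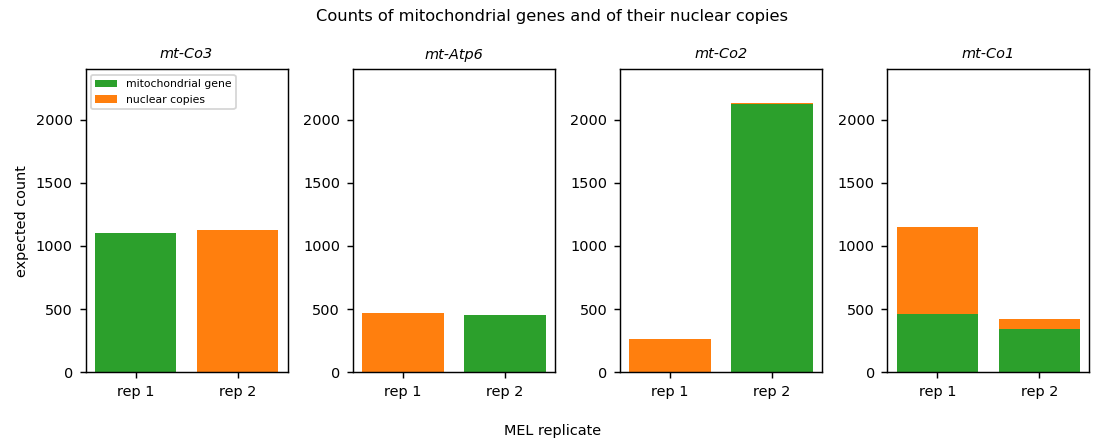
Expected counts (vertical axis) of 4 mitochondrial genes and, stacked on them, of the nuclear genes that share at least 25% of their 31-base words, in each MEL replicate. The summed counts of mt-Co3 were 1104 and 1128 and those of mt-Atp6 470 and 454, while those of mt-Co2 were 259 and 2137 and those of mt-Co1 1151 and 418.

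Over 1340 protein-coding genes with at least 10 summed counts, the chi-square between the libraries was 14.2 per degree of freedom, and the biological coefficient of variation was 0.989. Separate libraries exceed counting alone in any case, and reads are not independent molecules. Of 319 protein-coding genes with at least 20 counts in either library, 58 had less than 1 count in the other. In the first of 6 correlations, across 43346 genes, log2(TPM + 1) gave a Pearson r of 0.538 and a Spearman rho of 0.556, a description across genes that are not independent replicates. Over 3442 protein-coding genes with a count in both libraries, r was 0.400 and rho 0.344. Over 7192 with a TPM of at least 1 in either, r was 0.0475, a selection that keeps genes seen in 1 library and so lowers r.

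Gene lists mostly lay within the range of random lists. Of 16 lists with enough protein-coding members, ribosomal protein and reference genes lay outside the central 95%, and neither did on TPM with a pseudocount of 1. Ribosomal protein genes had a median log2 ratio of replicate 2 over replicate 1 of -0.59, with 40 of 64 members below 0 and 24 above, at percentile 0.795 of matched random lists (4.37 on TPM). Reference genes had a median of 1.06, at percentile 98.5, with 8 of 13 members above 0 (79.1 on TPM). The histone median was 0.58 at percentile 89.5, and 4.69 at percentile 100 on TPM. Haem synthesis had -0.59 at percentile 10.2, with 18.2% of random lists at the same value, and cell cycle genes had 0.57 at percentile 87.5. At a prior count of 2, 1 count against 0 gives a ratio of -0.59 or 0.58 by itself. The ribosomal, haem and histone medians are therefore the values of a single count and do not measure the size of a shift. Medians of the other lists lay between -0.75, for amino acid and unfolded protein stress, and 0.42, for erythroid factors, at percentiles from 9.67 to 77.4.

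Transcript shares could be given for 5 of the 20 fixed genes, those with at least 5 counts in each library, a minimum set after the counts had been seen. The transcript Gata1-201 held 100% of Gata1 in both libraries, with 57 and 5 counts, but 65.9% ± 31.5 on posterior means. Ldb1-204, a retained-intron transcript, had 45.6% ± 29.6 (SD, n = 2), the coding Ldb1-208 25.4% ± 6.79 (9.48% ± 2.73 on posterior means) and the coding Ldb1-205 21.8% ± 30.8. The glycolytic gene Pkm was assigned to Pkm-201 at 90.0% ± 14.1 and to Pkm-202 at 10% ± 14.1, but at 66.7% ± 6.62 and 33.3% ± 6.62 on posterior means. Zfpm1-204, a processed transcript of 559 bases not annotated as coding, had 86.5% ± 8.45 of TPM. The coding Zfpm1-201 had 13.5% ± 8.45, at a TPM of 13.6 in replicate 1 and 12.8 in replicate 2. Their shares of expected counts were 52.4% ± 18.7 and 47.6% ± 18.7. The retained-intron transcript Spta1-202 had 74.3% ± 30.9, and Spta1-201 25.7% ± 30.9. Bounds for the transcripts concern the posterior mean, such as 23.1 to 38.9 around 30.95 for Gata1-201 in replicate 1, where TPM was 381.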

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

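Signal outside the mouse genes exceeded the 3 counts that a count of 0 allows. The phiX174 row, a bacteriophage genome used as a sequencing control, held 204066 expected counts in replicate 1 and 177813 in replicate 2. Rows with numeric identifiers, which name no gene, held 361 expected counts in replicate 1 and 103 in replicate 2, yet 11.6% and 3.80% of TPM. The 96 spike-in rows held 0 counts in both libraries, although the labels name spike-ins, which allows up to 0.00125% of counts in replicate 1 and 0.00137% in replicate 2. No biological explanation was tested.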

How the results depend on the processing

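Settings that concern copies, mouse genes alone, gene length, counts in either replicate and coarser bins were chosen after the data were seen, as was leaving mitochondrial genes out of the correlation, noise and 2-fold results. The cause of a shift was not tested unless the setting itself gives it.

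Posterior mean TPM, above 0 without a count by construction, gave 14727 detected genes, 55 erythroid members and 42 members of other cell types. It gave shares of 0.602% for mitochondrial genes, 0.200% for ribosomal proteins and 0.791% for the 10 most abundant genes. Detection without 1 replicate ranged from 5288 to 5388 genes, and was 3 members of other cell types either way. At least 1 count in either replicate gave 54 erythroid and 5 other members, while a TPM of 5 and FPKM each gave 0 other members. Against detected genes as background, 3 lists in place of 13 had a median above the central 95% of random lists, those of Friend leukaemia, cell cycle and ribosomal protein genes, and no erythroid list did. The fixed lists kept their undetected members against that background, which lowers their percentiles.

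Shares of expected counts were 1.85% for mitochondrial genes, 0.378% for ribosomal proteins and 3.07% for the 10 most abundant genes. Over mouse genes alone, shares of TPM were 14.2%, 4.00% and 22.5% for these. Over protein-coding genes without mitochondrial genes, they were 7.28% for ribosomal proteins, 0.244% for histones and 0.0331% for adult globins. The value for the 10 most abundant genes was 3.78% there, but it is the share of Eef1a1 alone. The others of the 10 were mitochondrial or not annotated as protein-coding, so it is not comparable with their other shares. The beta-like globin share had no value except 27.0% and 27.1% on posterior means, which rest on the prior alone.

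Pearson r was 0.553 with a pseudocount of 0.1, 0.599 on log2 CPM, 0.0475 over protein-coding genes at a TPM of 1 in either library and 0.0426 without mitochondrial genes. Spearman rho was 0.574, 0.0544 and 0.0532 in the last 3. The coefficient of variation was 0.918 without a filter, 1.74 at 100 summed counts and 0.977 without mitochondrial genes, and the noise test kept its side. Genes at least 2-fold apart numbered 2330 without a filter and 311 at a mean count of 10, which admit more genes.

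For phiX174, single lists and transcripts, 217 alternative values stayed within tolerance and 78 moved beyond it. The tolerance was the SD between replicates for shares, 1.5 times for counts and 0.5 for median log2 ratios. With 2 replicates, leaving 1 out never moves a share by more than that SD, so those values stayed within tolerance by construction. Medians near 0 of the iron, cytokine and G1 lists changed sign on TPM. Leaving out a library shifted the median of the haem synthesis, G1, noncoding and adult globin lists to 0. Low depth was not tested as the cause.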

Other observations

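The tests of summed copies, the opposite strand and low depth were chosen only after the result was seen, and the test of shared words before.

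Glycolysis and hypoxia genes were detected in both libraries in 9 of 16 cases (median TPM 11.3, percentile 99.9, and 3.4 among detected genes). The enolase gene Eno1 stood at 814 ± 844 with 6 and 74 counts, Ldha at 302 ± 169 and Hk1 at 211 ± 222. Heat shock genes were detected in 5 of 9 cases (median TPM 20.04, percentile 99.9, 45.1 among detected genes and 96.0 on posterior mean TPM), led by Hsp90ab1 and by Hsp90aa1 at 1116 ± 1011. Amino acid and unfolded protein stress genes were detected in 6 of 11 cases (median TPM 12.9, percentile 99.7, 12.2 among detected genes and 89.1 on posterior mean TPM). Ddit3 stood at 172 ± 182 and Asns at 128 ± 162, with 25 counts in replicate 1 and 2 in replicate 2. Cholesterol synthesis genes were detected in 5 of 11 cases (median TPM 5.04, percentile 97.1, 97.6 or 98.7 with a single library, 0 among detected genes and 8.97 on posterior mean TPM), with Cyp51 at 14.8 ± 10.8 and Hmgcr at 11.8 ± 16.7.

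Of 14 genes of the G1 machinery, 4 were detected in both libraries (median TPM 1.35, percentile 90.9, and a median of 0 in each library alone), among them Cdk4 at 133 ± 180, Cdk6 at 32.6 ± 3.68 and Ccnd2 at 16.3 ± 1.24. Immediate early genes had a median of 0, with Ier2 at 41.5 ± 46.9 and Egr1 at 0 and 12 counts. Of 10 interferon response genes, Stat1 alone had counts, 1 and 3. Xist had no count, and the Y-linked genes Uty, Eif2s3y, Kdm5d and Ddx3y had 38.4 ± 2.29, 52.5 ± 67.9, 6.24 ± 6.60 and 5.77 ± 0.438 TPM (list median 6.01, percentile 92.2). In the same order, counts of these Y-linked genes were 1.9 and 4, 4 and 1, 1 and 2, and 2 and 2. Among noncoding RNAs, Rn7sk stood at 134 ± 10.2 with 3 counts in each library, and Malat1 at 117 ± 11.9. In both libraries, 3 of 9 were detected (median TPM 4.54, percentile 94.98, and 47.6 with replicate 2 alone). Among detected genes the lists of G1, Y-linked and noncoding genes lay at percentiles from 0 to 0.47.

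Among mitochondrial genes with a mean count of at least 100, mt-Co2, mt-Co3 and mt-Atp6 were over 10-fold apart, and each had near-identical nuclear copies. Counts of mt-Co3 were 1104 and 0.93 while those of its copy Gm28437 were 0 and 1127, so that the sums were 1104 and 1128. Counts of mt-Atp6 were 0 and 454 and those of Gm10925 470 and 0. For 2 of these 3 genes, the sum over copies was within 1.5-fold, and reads divided differently between near-identical gene copies may account for these. The third, mt-Co2, was still 8.03-fold apart as a sum, and below that mean count, mt-Nd4l (0 and 112 counts) and its copy Gm10222 (40 and 0) were 2.66-fold apart.

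Most protein-coding genes at least 2-fold apart stayed so after summing. Of the 12 genes, 5 had copies, and summing brought 2 of these 5 within 2-fold, against 1 when the copies' libraries were exchanged, and took mt-Co1 from 1.36-fold to 2.80-fold. Reads divided differently between near-identical gene copies therefore stay open as a part of the cause. Nanog, Dcaf17, Aldoart1, Hsp90ab1, Dnmt1, Hspa9 and mt-Cytb had no copy at this word share. What set their counts stays open, and no biological explanation was tested, since the series has 1 group.

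Reference and ribosomal protein genes with 0 or 1 count were weighed against 3 explanations. In 52 pairs of antisense protein-coding genes, 1 of each was chosen by symbol from families that are mostly housekeeping (ribosomal, respiratory, proteasome and heat shock genes among them, and Alas2), and the partners held 16.6% of counts (bootstrap interval 6.09 to 34.8), or 10.6% without partners from these families. The partner held more counts in 14 pairs, fewer in 29 and as many in 9. These values argue against reads counted on the opposite strand across a library. Genes with antisense exon overlap nevertheless held a count more often (45.0% against 30.8%, and 41.7% against 23.0% among shorter genes). Only 3 of the low genes had an antisense partner. Of 54 ribosomal protein values predicted at 5 or more counts from the other library, 14 lay at 0 (25.9%, exact interval 14.96 to 39.7). Low depth alone was set to allow at most 10%, so this argues against it for the values covered. A gene with at most 1 count in all cannot be predicted at 5, so the test could not cover the low genes. Low depth alone therefore stays open for those. The 22 low genes had a median of 71.5% of words in no other gene, against 76.6% in 43 genes with at least 10 counts (one-sided permutation p = 0.0485). Reads lost because they match several genes may contribute, though 19 of the 22 had over 50% of their words to themselves. The test cannot tell lost reads from reads assigned to another gene. Fractional expected counts, such as 168.13 for Eef1a1 in replicate 1, show that some reads were divided between genes.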
